A study of Homo sapiens with 12 samples.

How the data were processed

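The samples were 12 tumours of Li-7, a human hepatocellular carcinoma cell line, grown under the skin of nude mice. Per the labels, 6 came from mice injected with phosphate-buffered saline (control) and 6 from mice injected with 90 µg of galectin-9, 3 times a week. Galectin-9 is a secreted lectin that binds β-galactoside sugars on cell surfaces. Per the labels, total RNA was labelled with the single dye Hy5 and hybridised to arrays carrying 2019 human miRNA probes. The labels do not say that each tumour came from its own mouse, so p-values measure the spread between these samples.

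The deposited scanner files give, per the file headers, the median signal intensity of each spot and the median intensity of the background around it, neither of them normalized. Each miRNA probe had 1 spot per array. A deposited table of the authors' processed values fills 279 of the 2019 probes, and its rows were matched to the scanner files by probe ID. Its values are intensities on a linear scale, with a median of 447.1 in each of the 12 columns. Quantile normalization between arrays gives equal medians, as does scaling to 1 common median. Set against the quantile averages of the scanner signals for the same probes, the authors' sorted values for control replicate 1 differed by a median of -250.3 units. The software and the rule by which the 279 probes were chosen are not given in the sources used here.

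Signal intensities were background-corrected with normexp (offset 50), quantile-normalized over the human probes and put on the log2 scale, with limma 3.58.1 in R 4.3.3. A probe counted as detected on an array when its signal exceeded the mean plus 2 SD of 949 blank and negative-control spots, after 5% of these spots were trimmed from each end. Probes detected on at least 6 of the 12 arrays were tested, which left 440. The groups were compared with limma (lmFit and eBayes), with group as the only factor, and p-values were adjusted by the Benjamini-Hochberg method. The threshold was an adjusted p of 0.05. Fold changes are galectin-9 over control, with 95% confidence intervals from the limma fit. The number of arrays limits their precision, and log2 differences of dim probes are understated by the offset. The probe for miR-4454 was saturated on all 12 arrays and received no call. Control spots were left out after background correction.

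The design, the alternatives, 21 miRNA lists and the rule for naming miRNAs were fixed before the data were examined. Named are the 12 probes with the largest absolute log2 fold change in each direction among those past the threshold, all tested arms of miR-21, miR-122, miR-210, miR-221, miR-222, miR-224 and miR-1246, and of each list up to 4 tested members with the largest absolute change. The lists were miRNA families and clusters, miRNAs often raised or lowered in liver cancer, markers of other cell types a subcutaneous tumour could hold, and entries overlapping structural RNAs. Lists with at least 3 tested probes were compared with the other tested probes by camera with its preset correlation of 0.01. Camera with an estimated correlation was an alternative, as was fry, which tests whether a list's members move one way on balance and does not compare them with other probes. A probe joined a list by its name, so the probe shared by miR-199a-3p and miR-199b-3p joined none. Members of a family differ by few bases and can cross-hybridise. Many mature miRNAs have the same sequence in mouse and human, so a human probe can also read RNA of the host. The division of miRNAs by their number in the name (under 1000, or 1000 and over) was made after the values were seen.

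The test was tried on simulated data with the means and spreads of the 440 tested probes. At 1.25-fold 47.8% of changed probes were called, at 1.5-fold 88.1%, at 2-fold 100%, and 1.67% of unchanged ones were. With no probe changed, 0% were called, and with the miR-30 family moved, 1 of the 19 lists tested was called. The simulated probes were drawn independently of each other and were not normalized, while the estimated correlation within real lists reached 0.884. The simulation therefore cannot show how often camera calls lists by chance in these data. Other normalizations, background corrections, filters, models and the authors' values were tried as alternatives, and each array was left out in turn. Slide and scan date were not tested as a block, since the files used here name neither. They do give a position on the slide: controls 1 to 4 lay at position 1 and controls 5 and 6 at position 3, galectin-9 arrays 1 to 3 at position 2 and 4 to 6 at position 4. If a position holds 1 array, the arrays came from more than 1 slide, and differences between slides were not modelled. Each position held 1 group only, so no comparison within a position was possible, and position was added to the model as a random block and as a linear covariate after the data were seen. Scaling each array to its spike controls, and testing the lists only among probes numbered under 1000, were also added then.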

Results

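MicroRNA levels were measured in 12 Li-7 tumours grown under the skin of nude mice, 6 from mice given saline and 6 from mice given galectin-9. The series title names the growth of hepatocellular carcinoma under galectin-9 as its subject, and the comparison asked which miRNAs differed in the treated tumours. Of 2019 human miRNA probes, 491.7 ± 21.7 were detected per control array and 481.7 ± 69.9 per galectin-9 array (SD, n = 6 each), a difference that did not pass a two-sided exact permutation test (p = 0.755). The signal of blank spots was 223.2 ± 5.85 units in controls and 223.7 ± 6.56 with galectin-9 (SD, n = 6; exact permutation p = 0.931). The median local background was 180.5 ± 9.83 units in controls and 166 ± 12.2 with galectin-9 (exact permutation p = 0.0606, adjusted 0.106). It fell from position to position, with 184 to 189 at position 1, 174 to 180 at 2, 167 to 169 at 3 and 153 to 156 at 4. Controls at position 3 lay below galectin-9 arrays at position 2, so group alone does not give this order. Since each position held 1 group, an effect of group besides that of position cannot be separated. Between any pair of arrays, the correlation across the 440 tested probes lay between 0.907 and 0.991.

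In the quantile-normalized fit, galectin-9 tumours had higher signal for a group of miRNAs led by miR-1246. Their signal was lower for miR-199a, miR-125b, miR-10a, miR-30c and miR-126. miR-1246 rose 2.47-fold (95% confidence interval 1.82 to 3.35, adjusted p = 0.000693 by limma), from a normalized log2 intensity of 9.78 ± 0.31 to 11.09 ± 0.45 (SD, n = 6). It is 1 of 4 tested entries overlapping structural RNAs, and the other 3 did not pass. Whether its probe reads a miRNA or a piece of such an RNA was not tested. The probe shared by miR-199a-3p and miR-199b-3p had a fold of 0.467 (0.310 to 0.706, adjusted p = 0.00742), and miR-199a-5p, a miRNA of mesenchymal cells, one of 0.489 (0.330 to 0.726, adjusted p = 0.00785). With each array scaled to its spike controls, miR-199a-5p, the shared probe, miR-125b-5p and miR-126-3p did not pass (limma adjusted p = 0.0591, 0.0584, 0.154 and 0.112). Their log2 changes there were -0.93, -1.01, -0.74 and -0.59, while miR-10a-5p and miR-30c-5p stayed called. In all, 111 of the tested probes were higher and 102 lower with galectin-9, and 226 passed in neither direction. Of these, 3 higher and 2 lower probes reached 2-fold, against 1 and 0 without background correction, 11 and 2 with plain subtraction and 22 and 7 with the authors' values.

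Among the largest rises, miR-1229-5p reached 2.02-fold and miR-6125 2.01-fold, followed by miR-4688, miR-4732-5p, miR-4741, miR-1233-1-5p, miR-4442, miR-4459, miR-4467, miR-4651 and miR-4787-5p at folds of at least 1.85 and under 2. With linear position miR-4442 and miR-4732-5p were at log2 changes of 0.57 and 0.56 against 0.92 and 0.98 and did not pass (adjusted p = 0.145 and 0.226). miR-1246, miR-6125, miR-4741, miR-4459, miR-4651 and miR-4787-5p were higher on all 6 galectin-9 arrays than on any control. Among the falls, miR-125b-5p had a log2 change of -0.88, miR-10a-5p, a miRNA encoded within a HOX cluster, -0.84, miR-30c-5p -0.74 and miR-379-5p -0.73. miR-126-3p, enriched in endothelial cells, fell by 0.70 on the log2 scale, and miR-4443, miR-200a-3p, miR-4521, miR-27a-3p and miR-23a-3p followed at -0.66 to -0.57. Of these, miR-4521 was detected on only 3 of 6 galectin-9 arrays. Across all tested probes, 42 had every galectin-9 array above every control and 29 had every one below, where chance gives 0.216% of probes in either direction together.

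**Figure D1:**
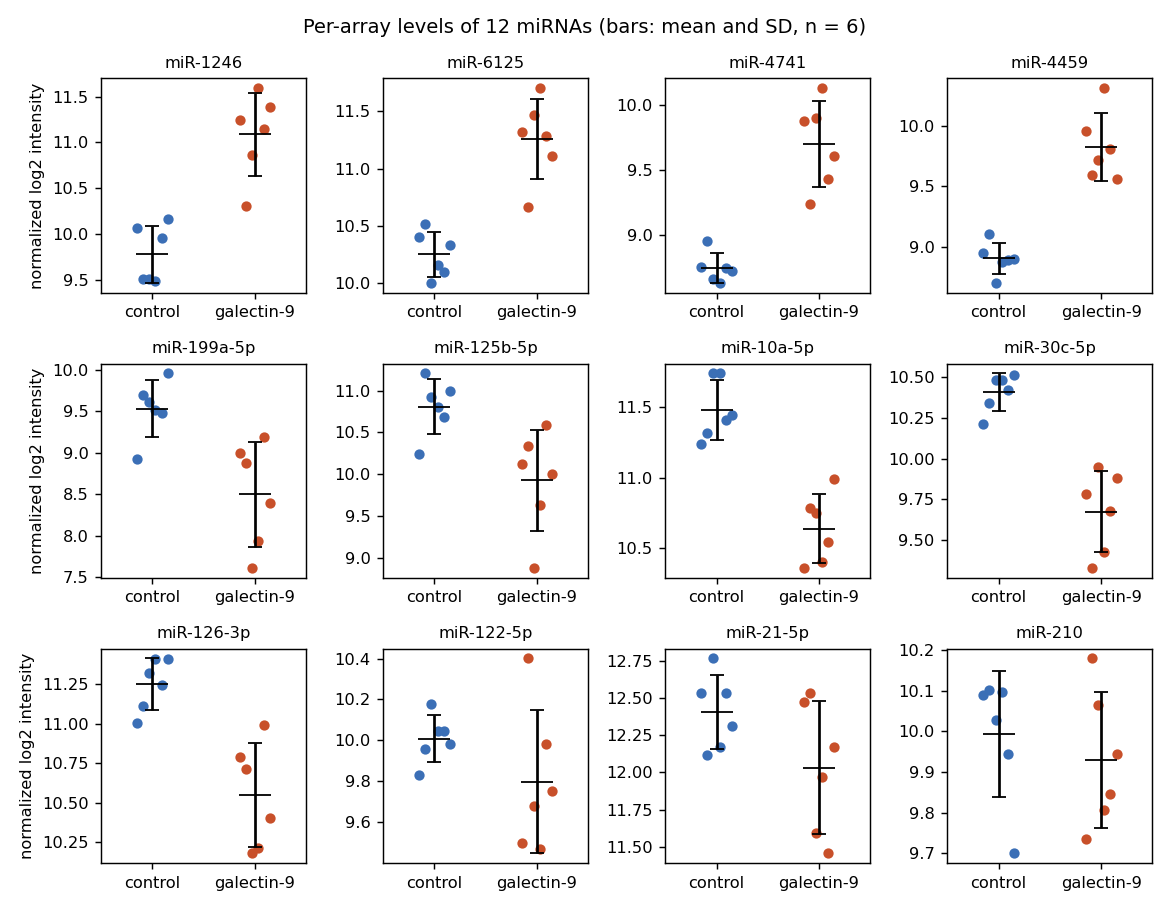
Normalized log2 intensity of 12 miRNAs on each array (points), with the mean and SD of 6 arrays per group (bars). The galectin-9 points of miR-1246, miR-6125, miR-4741 and miR-4459 lie above all controls, while those of miR-122-5p, miR-21-5p and miR-210 overlap them.

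Rises and falls divided by miRNA number, which follows the order of registration, so that many abundant, conserved miRNAs have low numbers. Of 258 tested probes numbered under 1000, 96 fell and 18 rose, among them miR-494, with a median log2 change of -0.26. Of 181 numbered 1000 and over, 93 rose and 6 fell, miR-4443 and miR-4521 among the latter, with a median of 0.35. The mean log2 intensity of the higher-numbered probes minus that of the lower-numbered was -0.39 ± 0.07 on control arrays and 0.17 ± 0.23 on galectin-9 arrays (SD, n = 6; exact permutation p = 0.00216, the smallest that 6 against 6 arrays can give, adjusted p = 0.00758 over 7 array measures). Since the division by number was made after the values were seen, that p describes the pattern and is no independent test of it. With each array scaled to its spike controls alone, 38 probes were higher and 4 lower, 90.5% of calls higher in place of 52.1%, and without normalization between arrays limma called 0 (135 at an unadjusted p under 0.05). The medians for numbers under 1000 and for 1000 and over were -0.21 and 0.37 with spike scaling and -0.11 and 0.48 without normalization. Without normalization miR-1246, miR-6125 and miR-4459 had log2 changes of 1.51, 1.21 and 1.08 (adjusted p = 0.0531 each) and miR-199a-5p one of -0.83 (adjusted p = 0.0973). Slide position and group could not be separated, and a linear position term left 68 probes higher and 44 lower.

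**Figure D2:**
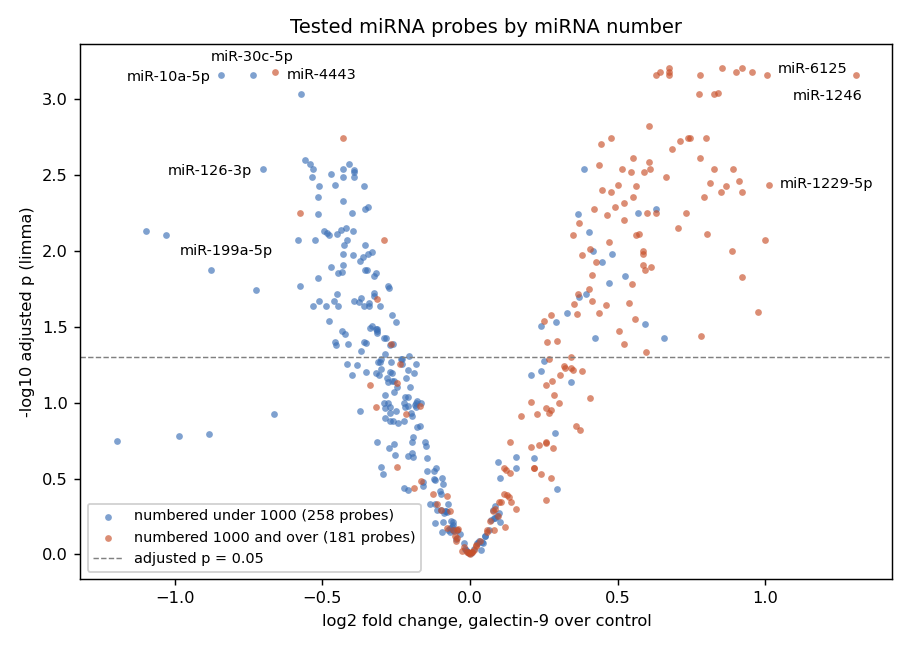
Each point is a tested probe, with its log2 fold change (galectin-9 over control) against -log10 of limma's adjusted p, coloured by miRNA number. Of the probes numbered 1000 and over 93 rose and 6 fell, and of those numbered under 1000 18 rose and 96 fell.

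**Figure D3:**
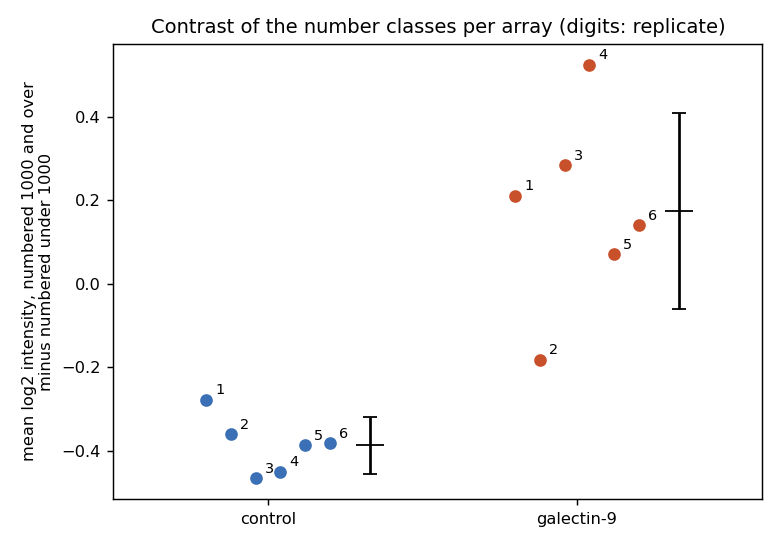
Mean log2 intensity of the probes numbered 1000 and over minus that of the probes numbered under 1000 on each array, with the mean and SD of 6 arrays per group. Galectin-9 replicate 2, at -0.18, lies nearest to the controls, the highest of which is at -0.28.

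In the first fit all 7 tested members of the miR-30 family fell, among them miR-30c-5p (fold 0.600), miR-30d-5p (0.726), miR-30e-5p (0.744) and miR-30b-5p (0.770). The call of miR-30b-5p ended with median scaling (log2 change -0.23 against -0.38, adjusted p = 0.196), cyclic loess (-0.16, adjusted p = 0.236), linear position (0.112), no filter on dim probes (0.0613) and the replicate block (0.0542). Of the miR-17-92 cluster and its paralogs, which promote cell cycling, 11 of 19 fell and none rose, with miR-106b-5p, miR-93-5p, miR-20a-5p and miR-20b-5p at log2 changes of -0.54 to -0.53. In the let-7 family, which restrains RAS and MYC, let-7g-5p, let-7i-5p, let-7c and let-7e-5p fell and 6 members did not pass. Camera called these lists lower (adjusted p = 0.0189, 0.00347 and 0.0445), and with an estimated correlation each had an adjusted p = 0.579. All their members are numbered under 1000, where 96 of 258 probes fell, and against that class alone the calls ended (adjusted p = 0.320, 0.320 and 0.741). Adjusted over the list alone, 7, 12 and 4 members fell. Leaving out 1 array ended the call of let-7c in 3 of 12 fits and that of let-7e-5p in 7, and the let-7 list was called in 7. Median scaling and cyclic loess ended both calls (adjusted p = 0.105 and 0.147 for let-7c, 0.124 and 0.129 for let-7e-5p) and that of the list, with let-7c at -0.26 against -0.48 and let-7e-5p at -0.22 against -0.43 under cyclic loess. Without a filter on dim probes both calls ended too, and with linear position both and those of let-7i-5p, miR-30d-5p and miR-30e-5p. Of the calls named in these 3 lists, only that of miR-30c-5p stayed with spike scaling. There miR-106b-5p, miR-93-5p, miR-20a-5p and miR-20b-5p had limma adjusted p = 0.204, 0.173, 0.185 and 0.338.

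In the miR-15/16 family miR-195-5p, miR-16-2-3p, miR-497-5p and miR-16-5p fell, 4 of 9 tested, and in the miR-23/27/24 clusters miR-27a-3p, miR-23a-3p, miR-23b-3p and miR-24-2-5p, 4 of 7 (camera adjusted p = 0.0897 for either list). Leaving out 1 array, the second list was called lower in 4 of 12 fits, and the first was called without a filter on dim probes. In the epithelial miR-200 family miR-200a-3p fell, 1 of 5 (adjusted p = 0.281), while miR-200b-3p was at a log2 change of -0.42 (adjusted p = 0.0558) and passed without control replicate 2 (0.00814), without galectin-9 replicate 2 (0.0273) and in 4 other settings. miR-29b-3p was the 1 of 4 in the miR-29 family to fall (list adjusted p = 0.413) and miR-181b-5p the 1 of 4 in the miR-181 family (0.440), where miR-181a-5p passed too without galectin-9 replicate 2 (0.0159). None of the 3 probes of the cluster of miR-183, miR-96 and miR-182 passed (0.343), but miR-182-5p did without galectin-9 replicate 2 (adjusted p = 0.00453) and in 3 other settings, and miR-96-5p without control replicate 2 (0.0454) and with the authors' values (0.0415). Nor did any of 6 in the list of the miR-34 family and other p53-induced miRNAs pass (0.456). In the imprinted 14q32 cluster miR-379-5p, miR-411-3p and miR-299-5p fell and miR-494 rose, 4 of 13 (0.558). Of the probes named here, miR-411-3p, miR-299-5p and miR-16-2-3p were detected on 2, 1 and 3 of 6 galectin-9 arrays, so their falls rest partly on values below the detection limit. No probe of the chromosome 19 cluster was tested. Adjusted over the list alone, the counts of these families were the same. Leaving out 1 array ended the calls of miR-16-5p, miR-497-5p and miR-23b-3p in 8, 7 and 2 of 12 fits. These 3 calls also ended with median scaling, cyclic loess and linear position. Median scaling ended the calls of miR-24-2-5p and miR-181b-5p too, and linear position those of miR-181b-5p, miR-195-5p, miR-29b-3p, miR-299-5p and miR-494. Without a filter on dim probes miR-16-5p, miR-497-5p, miR-181b-5p, miR-299-5p and miR-494 did not pass, nor did miR-497-5p, miR-29b-3p and miR-299-5p with the replicate block. By exact permutation let-7e-5p, miR-16-5p and miR-497-5p did not pass, and miR-497-5p did not without background correction or with array weights. With spike scaling every call named for these families ended.

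Of 15 probes often raised in liver cancer 5 fell, among them miR-93-5p, miR-25-3p, miR-224-5p (fold 0.718, adjusted p = 0.00785) and miR-221-3p (fold 0.782, adjusted p = 0.00908). Of 13 often lowered 7 fell, led by miR-199a-5p, miR-125b-5p, miR-26a-5p and miR-195-5p. miR-21-5p (fold 0.772, 0.581 to 1.03, adjusted p = 0.113), miR-222-3p (0.878, adjusted p = 0.103), miR-21-3p (0.934), miR-224-3p (0.953) and the hypoxia-induced miR-210 (0.957) did not pass. Without galectin-9 replicate 2 miR-21-5p passed (adjusted p = 0.0426), miR-222-3p passed with the authors' values (0.0325) and without background correction (0.0499). miR-26a-5p did not pass with median scaling (log2 change -0.37 against -0.53, adjusted p = 0.122), cyclic loess (-0.26, adjusted p = 0.163), linear position (0.103) or without galectin-9 replicate 4 (0.0503), nor miR-221-3p and miR-224-5p with linear position (0.0827 and 0.0691). Camera called each list lower than the other tested probes (adjusted p = 0.0397, and adjusted p = 0.579 with an estimated correlation). The list often raised was not called with median scaling, without normalization, or with the replicate block, trended variances, linear position or spike scaling. The list often lowered was not called with the authors' values. Among probes numbered under 1000, of which 96 of 258 fell, neither was called (adjusted p = 0.741 each). Adjusted over the list alone, 5 and 7 fell. With spike scaling the call of every named fall in these lists ended.

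Among cell type markers, 6 of 9 stromal and vascular probes fell, including miR-199a-5p, miR-126-3p, and miR-143-3p and miR-145-5p of smooth muscle (folds 0.733 and 0.761). Camera called the list lower (adjusted p = 0.0195, and adjusted p = 0.579 with an estimated correlation), but not among probes numbered under 1000 (adjusted p = 0.320) or with the authors' values. When adjusted over the list alone, 7 fell. Of 4 leukocyte probes miR-142-5p and miR-342-3p fell, 3 adjusted over the list alone (list adjusted p = 0.149). miR-142-5p did not pass with median scaling (adjusted p = 0.126), linear position (0.0983), no filter on dim probes (0.0940) or the replicate block (0.0525). These 4 settings, cyclic loess and exact permutation ended the call of miR-342-3p. miR-146a-5p passed without control replicate 2 or galectin-9 replicate 4 (adjusted p = 0.0493 and 0.0107) and in 3 other settings, and miR-223-3p without galectin-9 replicate 5 (0.0469). No hepatocyte probe of 6 passed (0.456), and miR-122-5p, the main liver miRNA, had a fold of 0.865 (0.699 to 1.07, adjusted p = 0.225). Without galectin-9 replicate 2, miR-122-5p was called lower (log2 change -0.33 against -0.21, adjusted p = 0.0165), as was miR-192-3p (-0.35 against -0.28, adjusted p = 0.0192), which also passed with the authors' values, with array weights and without galectin-9 replicate 3, while miR-194-3p passed with array weights (0.0417). Of 5 erythroid probes miR-486-3p rose, 0 adjusted over the list alone, and with median scaling its log2 change was 0.20 against 0.29 (adjusted p = 0.210). It did not pass either without background correction, without a filter on dim probes, with the replicate block, by exact permutation or with linear position, and miR-451a did not pass (fold 0.815, adjusted p = 0.295). Without galectin-9 replicate 3 miR-486-5p was called lower (adjusted p = 0.0115). The list had a median of -0.21 while camera's direction was up (adjusted p = 0.967). The 4 skeletal muscle probes, miR-1, miR-133a, miR-133b and miR-206, had log2 changes of -0.66 to -1.19 with wide spread between arrays, and none passed (list adjusted p = 0.343). The list was called lower without normalization and without a filter on dim probes, and miR-206 with the replicate block (adjusted p = 0.0366) and without control replicate 1 (0.0438). Of the 4 entries overlapping structural RNAs, miR-1246 rose and miR-1260a, miR-1260b and miR-3676-3p did not pass (0.773). miR-3676-3p was called lower without control replicate 4 (0.0229), without galectin-9 replicate 1 (0.0469) and in 4 other settings, and miR-1260b with median scaling (0.0111). No epidermis probe was tested. Leaving out 1 array ended the calls of miR-342-3p and miR-486-3p in 6 and 5 of 12 fits. Both calls, and those of miR-142-5p, miR-143-3p and miR-145-5p, ended with spike scaling.

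**Figure D4:**
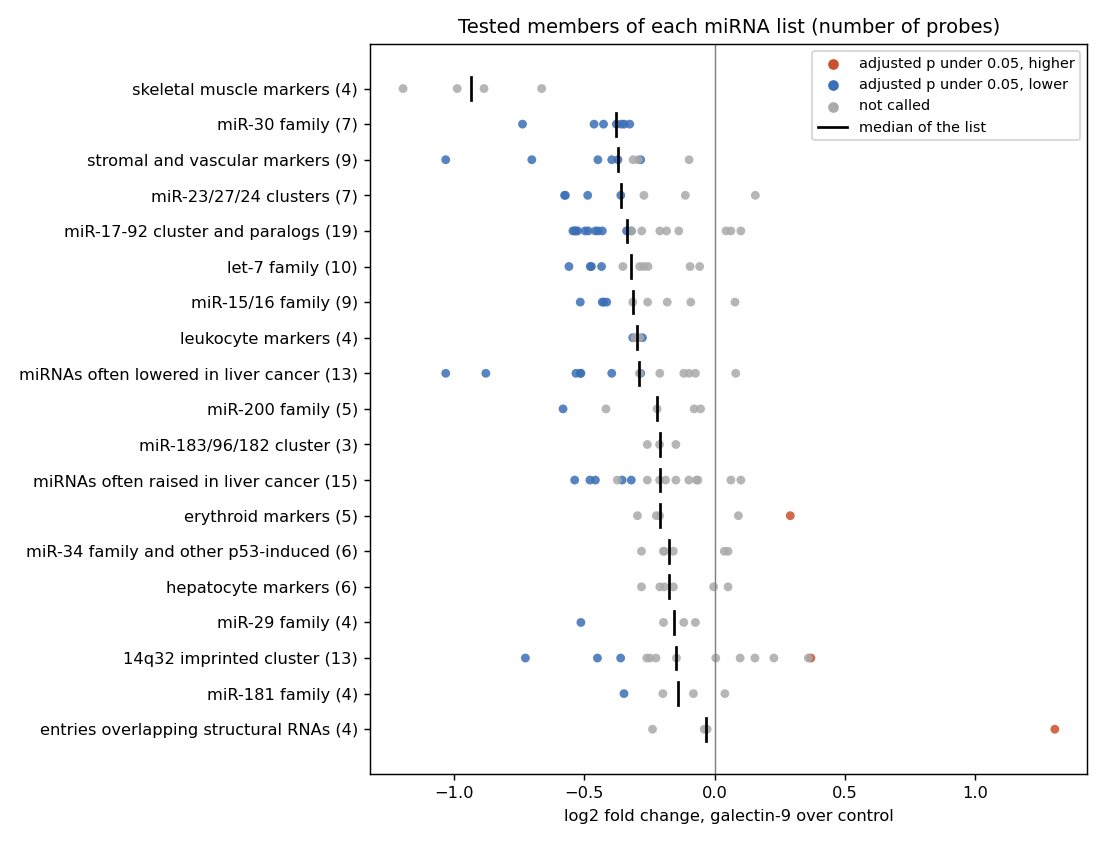
Log2 fold change (galectin-9 over control) of every tested member of each list, with the list's median as a black bar; coloured points passed an adjusted p of 0.05. All 7 miR-30 probes fell in this fit, miR-30b-5p with neither median scaling nor cyclic loess, and the skeletal muscle markers had the lowest median, -0.94, with no member past the threshold.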

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

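The tests of the structural RNA entries and of an exchange with a control array, the SE of the spike-scaled median and the addition of the shared miR-199 probe were chosen only after the results were seen. In 14 of 186 sets of 6 values, 1 array stood far from the other 5 relative to the whole range, where chance gives about 9.3. Among controls the gap as a share of the range was 0.839 for miR-379-5p (replicate 1, low), 0.683 for miR-16-5p (replicate 5, high), 0.627 for miR-146a-5p and 0.645 for miR-29c-5p (both replicate 4, high), and 0.639 for miR-181d (replicate 1, high). miR-1260b reached 1 in control replicate 2, where the other 5 arrays share 1 normalized value. Among galectin-9 arrays it was 0.759 for miR-27a-3p, 0.703 for miR-16-2-3p and 0.777 for miR-34a-5p (replicate 3, low), 0.827 for miR-486-5p (replicate 3, high), 0.747 for miR-24-2-5p, 0.628 for miR-222-3p and 0.630 for miR-181a-3p (replicate 4, low), and 0.683 for miR-29c-5p (replicate 6, high). Of 15 kinds of control spot with signal on all arrays, 11 were lower in mean log2 signal and 9 in group median with galectin-9, and none passed. The lowest p was that of the first spike control, which also enters spike scaling and was higher with galectin-9 (log2 difference 0.13, exact permutation p = 0.0563, adjusted 0.755).

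Of 100 of the 462 splits of the 12 arrays into 6 and 6, only 1, the real one, gave as many probes higher (111) or lower (102). The highest other split gave 88 in 1 direction. That number depends on which splits are drawn: 3 drawn splits that exchanged galectin-9 replicate 2 with a control gave 39 to 88, and the highest of all the others gave 8. For the lists, 17 of the 100 splits called as many as the real 6, and the highest other called 10, so chance cannot be excluded for the number of lists called.

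The first pattern is that miRNAs numbered 1000 and over were higher and those numbered under 1000 lower. A linear trend along the slide positions is argued against, since the group difference of the contrast stayed at 0.51 (SE 0.12) with position in the model, but any other effect of position cannot be told apart from the group. Quantile normalization could turn a rise of 1 class into a fall of the other: with spike scaling the median of the lower-numbered probes was -0.21, below the bound of -0.1 set beforehand, yet the per-array medians differed by -0.12 with an SE of 0.17, so this stays open, while the difference between the classes remained at 0.60 (SE 0.10, exact permutation p = 0.00216). The classes were chosen after the values were seen, so that p is no independent test of the pattern. A lower share of intact miRNA in the labelled RNA also stays open, since the entries overlapping structural RNAs had a median of -0.034 with members that went both ways. That median was -0.115 with median scaling and 0.029 without normalization. The tested entries are themselves numbered 1000 and over and include miR-1246, the largest rise, so they cannot decide this. Probe sequences are not in the files used here, so the base composition of the probes was not set against the classes. A response of the tumours to galectin-9 is among the open explanations.

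The second pattern is that galectin-9 replicate 2 lay near the controls, at a contrast of -0.18. An exchange with a control array is argued against, if a treated tumour would resemble the other 5 galectin-9 arrays. The highest control was at -0.28 and the lowest of those 5 at 0.07. Loss of dim probes is argued against too: on the brighter 148 probes the contrast of galectin-9 replicate 2 was 0.19, below the lowest of the other 5 at 0.52. A single wrong label, or a weaker response in that tumour, was not tested and may hold. Nor was an exchange with control replicate 1, the control at -0.28, tested by itself. Without galectin-9 replicate 2, 126 probes were higher and 119 lower.

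The third pattern is that stromal and vascular markers were lower, for which fewer host stromal and vascular cells are a candidate explanation. Among probes numbered under 1000, limma's camera gave the list a p of 0.0533. Its median was -0.37 against -0.25 for the others, at percentile 5.76 of 10000 random lists of its size. By the rule set beforehand these values argue against the explanation, though by little. Camera's p was not under 0.05, and the median lay above -0.40, the 2.5th percentile of random lists. The list leaves out the called probe shared by miR-199a-3p and miR-199b-3p. That probe was among the largest falls and was added only after the results were seen. With it camera's p was 0.0285, and 0.328 with an estimated correlation. A probe picked in this way gives no independent support. With values this close to the bounds, the explanation is left open.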

How the results depend on the processing

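The 111 higher and 102 lower probes stayed within 1.5 times under median scaling, cyclic loess, 3 other background corrections, the 12-array filter, the authors' values, quality weights, trended variances and exact permutation per probe, and every call shared with the first fit kept its direction. Without normalization between arrays limma called 0 higher and 0 lower (135 at an unadjusted p under 0.05) with class medians of -0.11 and 0.48 against -0.26 and 0.35, and without a filter on dim probes 66 were lower, with 2019 probes tested. Alternatives chosen after seeing the data gave 38 higher and 4 lower (spike controls) and 68 higher and 44 lower (linear position), while position as a random block gave 126 and 130 with a consensus correlation of -0.086; below 0, this narrows the errors and removes no shared position effect, so the named calls it added are not counted in the report. The cause of these shifts was not tested. Leaving out each array in turn gave 97 to 126 higher, 82 to 119 lower and 4 to 7 lists. The 6 lists became 3 with the authors' values, 0 with an estimated correlation, 10 by fry and 0 among probes numbered under 1000, and in the other settings 4 to 8. The class medians became -0.17 and 0.19 without background correction, and on the 278 unsaturated probes of the authors' table -0.31 and 0.52 became -0.48 and 0.67 with their values. Of 89 named miRNAs, 55 were called and no called direction reversed, but every call ended in at least 1 setting. Leaving out normalization ended all 55 calls and spike scaling ended 43. In settings besides these, 23 ended: 22 with linear position, 12 with median scaling, 11 without a filter on dim probes, and 8 each with cyclic loess and the replicate block. Leaving out 1 array ended 9 calls (miR-16-5p, miR-497-5p, let-7e-5p, miR-342-3p, miR-486-3p, let-7c, miR-23b-3p, miR-26a-5p and miR-4732-5p) and added 12 of the 34 others. Of the lists, let-7 was called in 7 of 12 such fits, those often lowered and raised in liver cancer in 10 and 11, the other 3 in 12, and the miR-23/27/24 clusters, not called with all arrays, in 4. Equal replicate numbers gave no clear sign of pairing: same-number correlations were -0.226 to 0.292, with 2 of 6 over 0.1 and 0 of 6 controls closest to their own number. Whether arrays of equal number were processed together is not given, and these values cannot exclude it. A replicate block gave 94 higher, 76 lower and 5 lists. The difference in detected probes, -10, was 6 and -5 under the other detection rules and -28.9 to 10.1 leaving out each array, never past the threshold. The slide or scan date block was not run. Signal over background limits the dim probes: 298 of the 440 tested were detected on all 12 arrays.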

Other observations

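The skeletal muscle markers varied widely within both groups. On control arrays miR-133b ranged from a normalized log2 intensity of 6.33 (replicate 1) to 10.81 (replicate 3), and on galectin-9 arrays from 6.63 (replicate 3) to 9.17 (replicate 2). miR-1 was likewise 6.70 in control replicate 1, 9.66 in control replicate 3 and 8.75 in galectin-9 replicate 2.

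miRNAs encoded near each other did not always move alike. By the GRCh38.p14 gene table, 86.6% of tested probes matched a single miRNA gene, and 13 groups of neighbouring genes held at least 3 tested probes; camera called none (lowest adjusted p = 0.193). miR-4732-5p lies next to the erythroid miR-144 and miR-451a and rose by a log2 change of 0.98, while miR-451a was at -0.30. The call of miR-4732-5p ended with a replicate block (adjusted p = 0.0673), by exact permutation (0.0690), without control replicate 4 (0.0528), without normalization (0.0957) and with spike scaling (0.0793), and with linear position its log2 change was 0.56 (0.226). In the miR-106b, miR-93 and miR-25 group 3 of 5 probes fell, with a median of -0.46. In the X-linked group that includes miR-532, miR-500a and miR-660, 3 of 11 fell, with a median of -0.12, and the group of miR-424, miR-503 and miR-542 had 0 of 4 changed, with a median of 0.01.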
